A study of Homo sapiens with 6 samples.

How the data were processed

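The data were gene expression values from Affymetrix PrimeView arrays, 3' arrays on which each gene is read by 1 or more probe sets. Biotin-labelled cRNA had been prepared from total RNA of MM.1R cells, a human multiple myeloma line that is resistant to glucocorticoids. There were 6 arrays. In 3 of them the cells had been infected with a control short hairpin vector (shCtrl), and in the other 3 they had been given epirubicin hydrochloride, per the labels. Groups and replicate numbers were taken from the sample titles. The dose and the length of treatment are not given in the sources used here, and nothing says whether the 3 arrays of a group came from separate cultures. The p-values therefore measure only the spread between these samples, which may be technical.

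The table used was the authors' deposited log2 expression values, 1 value per probe set and array, for 47481 probe sets. The log2 scale was read from the values, which ran from 1.41 to 13.73 with none missing, since no label states it. The affy package, without a version, is the only tool that the submitters' processing notes name; the background correction, the normalization and the summary of probes are not given in the sources used here. Array medians lay between 5.52 and 5.57, and no further normalization was applied. A normalization before deposit, if there was one, would remove any change in the total amount of RNA per cell, so all differences are read as relative to the bulk of transcripts. Scanner files, detection calls and scan dates were not used here: background and hybridization batches could not be examined, and the number of arrays limits the precision.

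Probe sets were named through the platform annotation. A single gene symbol was given to 43976 of them, several symbols to 1558 and none to 1947. Symbols were updated through Entrez gene numbers against the RefSeq gene table of GRCh38.p14, in which 43954 of the 43976 matched. For each of the 17534 genes the probe set with the highest mean over the 6 arrays was used, among those naming that gene alone; 6007 genes had 1 such probe set. Where the probe sets of a called gene disagreed, this is stated beside the gene.

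Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, all 6 arrays, no covariate), with Benjamini-Hochberg adjustment over the 17534 genes. A gene was called higher or lower with epirubicin at an adjusted p under 0.05 and a fold change of at least 1.3, the thresholds given in the series' design text, which also names an empirical Bayes linear model. The same fit was run on all 47481 probe sets. Fold changes are epirubicin minus control on the log2 scale, with limma's standard error (SE) and 95% confidence intervals (CI).

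For 24 gene lists the members called higher, lower or neither were counted, and each list was tested against all other genes with camera at a preset inter-gene correlation of 0.01, adjusted over the 24 lists. camera with an estimated correlation, and fry, were run as alternatives. The lists covered p53 targets, G2/M, G1/S, histones, DNA repair, the BCL2 family, anthracycline handling, plasma cells, the unfolded protein response, ATF4, interferon, NF-kB, immediate early genes, ribosome biogenesis, ribosomal proteins, oxidative phosphorylation, cholesterol synthesis, glycolysis and hypoxia, NRF2 and heat shock. A further 4 held markers of T and NK, myeloid, stromal and epithelial cells. Their members, the tests, the thresholds and the rule for naming genes were fixed before the data were examined.

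Genes are named by that rule. It takes the 10 genes with the largest change in each direction among those called, provided that the 3 arrays of 1 group all lie beyond the 3 of the other and that the higher group mean exceeds 5.54, the median of all values. It also takes up to 2 called members per list and direction under the same conditions, and 12 preset genes given whatever their result, of which 11 are reported and 1 is not analysed here. A few other genes, named to complete a count of 5 or fewer or as examples, were chosen after their values were seen, and each is marked as such where it appears.

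The fit was tested on simulated data with the real means and spread, in which 200 of the 17534 genes were changed, over 20 draws. It recovered 37.9% of genes changed 1.3-fold, 85.7% of those changed 1.5-fold, 97.5% at 2-fold and 99.9% at 3-fold, with a mean of 1.6 false calls per draw. Genes changed 1.3-fold lay on the fold threshold itself. In the real data 5106 genes had an adjusted p under 0.05 in limma at any fold. The adjustment was therefore stricter in the simulation, and these rates do not carry over directly to the real calls. For the list test, a list shifted by 0.3 on the log2 scale was called in 20 of 20 draws, and 0 unshifted lists were called. Genes were simulated independently of each other, so this cannot show how often the list test calls falsely when the genes of a list are correlated.

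Alternatives comprised the mean of a gene's probe sets, filters on dim genes, quantile normalization and median centring of the arrays, other variance priors, array weights, other fold thresholds, the replicate number as a block and leaving out each array in turn. A count of genes with at least 1 probe set called, and the interferon list without members shared with other lists, were added after seeing the data.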

Results

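Expression was measured in MM.1R cells, a glucocorticoid-resistant human myeloma line, on 3 arrays of cells infected with a control short hairpin vector and 3 arrays of cells given epirubicin, an anthracycline that poisons topoisomerase II. The submitters' stated purpose of the drug was to stop the cells from proliferating. The design gives 1 comparison, epirubicin against control. The labels name the vector for the control arrays alone, so drug and vector cannot be told apart by the labels, and every difference below is between these 2 groups as they stand. Arrays of the same group correlated at r = 0.998213 to 0.99847 across probe sets, and arrays of different groups at 0.994496 to 0.994729, where probe sets are not independent replicates. The first principal component held 70.9% of the variance and separated the groups, and the second held 8.34%.

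With epirubicin, ITGAM, the alpha chain of the integrin Mac-1 (CD11b), rose 13.4-fold, from a log2 value of 3.25 ± 0.09 to 6.99 ± 0.01 (SD, n = 3). The probe set used was the brightest of 3 over all 6 arrays, but not in control arrays. There another lay at 4.57, and it rose by 0.79 on the log2 scale. GADD45G, a growth arrest and DNA damage-inducible gene, rose 6.69-fold, the stress-induced transcription factor ATF3 rose 5.91-fold, and TNFSF9, the ligand of the costimulatory receptor 4-1BB, rose 5.11-fold. CDC20, an activator of the anaphase-promoting complex, was 4.88-fold lower, the helicase PIF1 4.60-fold lower and CCNB1, which encodes cyclin B1, 3.45-fold lower. Of 17534 genes, 765 were higher and 376 lower with epirubicin. The 3 arrays of 1 group lay beyond the 3 of the other in 43.8% of all genes, where chance would give 10%.

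The other genes with the largest increases were DRAM1, a lysosomal membrane protein of the autophagy pathway (log2 fold change 2.32, SE 0.08), PHLDA3, a repressor of AKT (2.15, SE 0.05), PMAIP1, which encodes the BH3-only protein NOXA (1.98, SE 0.03), the proteoglycan gene AGRN (1.94, SE 0.08), the kinase gene PLK2 (1.93, SE 0.06) and CHRNA1, the alpha subunit of the muscle acetylcholine receptor (1.93, SE 0.04). The adjusted p of these genes in limma ran up to 2.51e-05, that of AGRN. Among the decreases, the mitotic kinesin genes KIF20A and KIF14 fell by 1.69 (SE 0.03) and 1.17 (SE 0.04) on the log2 scale. LMNB1, which encodes lamin B1, fell by 1.39 (SE 0.04), the spindle protein gene FAM83D by 1.20 (SE 0.05) and the centrosomal kinase gene NEK2 by 1.18 (SE 0.04). CD38, a plasma cell surface enzyme and a target of antibodies in myeloma, fell by 1.18 (SE 0.05). MET, the receptor of hepatocyte growth factor, fell by 1.35 (SE 0.08), with 2 of its 6 probe sets called lower, and its mean over probe sets changed by -0.34, short of the fold threshold. The adjusted p of these 7 genes ran up to 8.95e-05 in limma, that of MET. AGRN had 1 of 2 probe sets called, ATF3 4 of 7 and CDC20 2 of 3. As means over all probe sets of a gene several of the largest changes were smaller, at 2.35 for ITGAM, 1.23 for ATF3, 1.00 for AGRN, -1.58 for CDC20 and -1.36 for PIF1, all still called, while GADD45G and CCNB1 have 1 probe set each.

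**Figure D1:**
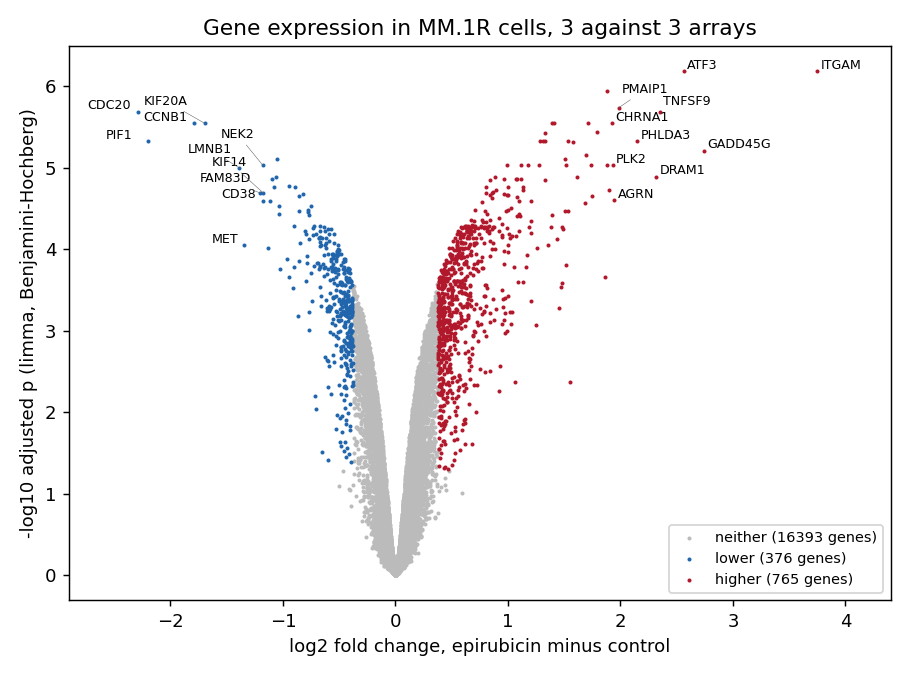
Each point is 1 of 17534 genes, with its log2 fold change (epirubicin minus control) on the horizontal axis and the negative log10 of its limma adjusted p on the vertical axis. The 765 genes called higher are red and the 376 called lower are blue, and the 20 named points run from CDC20 at -2.29 to ITGAM at 3.75.

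Changes of 2-fold or more were found for 85 genes upward and 19 downward, and of 4-fold or more for 6 upward and 2 downward. Without a fold threshold 5106 genes had an adjusted p under 0.05 in limma. Over all 47481 probe sets, 1735 were higher and 1242 lower. The series' design text states 1055 genes up and 761 down without saying how probe sets were counted; counting a gene once when at least 1 of its probe sets was called gave 969 higher and 694 lower, with 1 gene in both. The control level of the ITGAM probe set used lay below the lower quartile of every array (3.84 to 3.90), and without detection calls its fold depends on how the authors treated background.

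Genes regulated by p53 rose together. Of 48 measured p53 target genes, 39 were higher and 0 lower with epirubicin. The list's median log2 fold change was 0.83 (camera, adjusted p = 4.37e-30, and adjusted p = 0.0156 with an estimated correlation). CDKN1A, which encodes the cyclin-dependent kinase inhibitor p21, rose 3.68-fold, from 10.07 ± 0.01 to 11.95 ± 0.01 (SD, n = 3). MDM2, the ubiquitin ligase that targets p53, rose 2.11-fold (log2 fold change 1.08, CI 0.99 to 1.16) on all 11 of its probe sets. DRAM1 and PHLDA3 had the largest increases of the list. The 9 members that did not pass included GDF15 and BCL2L1, both chosen after their values were seen, at 0.36 and 0.31. Adjusted over the list alone, the counts were again 39 and 0.

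Of 20 genes of the BCL2 family, 4 were higher and 0 lower: PMAIP1, BBC3, which encodes PUMA (3.34-fold, log2 1.74, SE 0.05), and, named to complete the count after their values were seen, BMF (0.65, SE 0.06; 1 of 4 probe sets) and BAX (0.44, SE 0.03). All 4 encode proteins that promote apoptosis, and 3 of the 4 also stand in the p53 list. The other 16 members were called in neither direction, and proapoptotic members were not tested against antiapoptotic ones. The family median was 0.09 and its call was lost with an estimated correlation (adjusted p = 0.00568 in camera, and adjusted p = 0.129 with an estimated correlation). The antiapoptotic genes MCL1 and BCL2 were not called, with log2 fold changes of 0.08 (CI 0.004 to 0.15, limma adjusted p = 0.111) and 0.30 (CI 0.21 to 0.39), the latter a 1.23-fold difference under the fold threshold.

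Genes of G2 and mitosis fell. Of 48 measured members 35 were lower and 0 higher. The median log2 fold change was -0.61 (camera, adjusted p = 1.44e-33, and adjusted p = 0.0125 with an estimated correlation). CDC20 went from 9.15 ± 0.05 to 6.86 ± 0.05 and PIF1 from 7.79 ± 0.02 to 5.59 ± 0.11 (SD, n = 3). In contrast, 49 of 51 genes of G1/S and DNA replication did not pass, 0 were lower, and the list was not called (median 0.03, camera, adjusted p = 0.357). The 2 that rose were GINS4, a subunit of the replicative helicase (0.59, SE 0.05), and PCNA, the sliding clamp of DNA polymerase (0.45, SE 0.03). The mean of the G2/M members minus the mean of the G1/S members per array was -0.148 ± 0.005 in control arrays and -0.895 ± 0.008 in epirubicin arrays, a difference of -0.747 (SD, n = 3; exact permutation test, two-sided p = 0.1, the smallest that 3 against 3 arrays allow).

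Of 57 replication-dependent histone genes, 1 was higher, H2BC12 (0.85, SE 0.05; 1 of 2 probe sets, with a mean of 0.41 over both), and 1 lower, H4C2, named after its value was seen (-0.41, SE 0.06). The list was not called (median -0.03, camera, adjusted p = 0.128). Of 33 genes of homologous recombination and Fanconi repair, 1 was lower, NBN, a subunit of the MRE11 complex (-0.40, SE 0.04; 3 of 5 probe sets), and 0 were higher. That list was not called either (median 0.01, camera, adjusted p = 0.930), and its median and mean lay above 0 while the test's direction was downward. The direction is relative to all other genes and not to 0, and the median over all genes was 0.02.

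**Figure D2:**
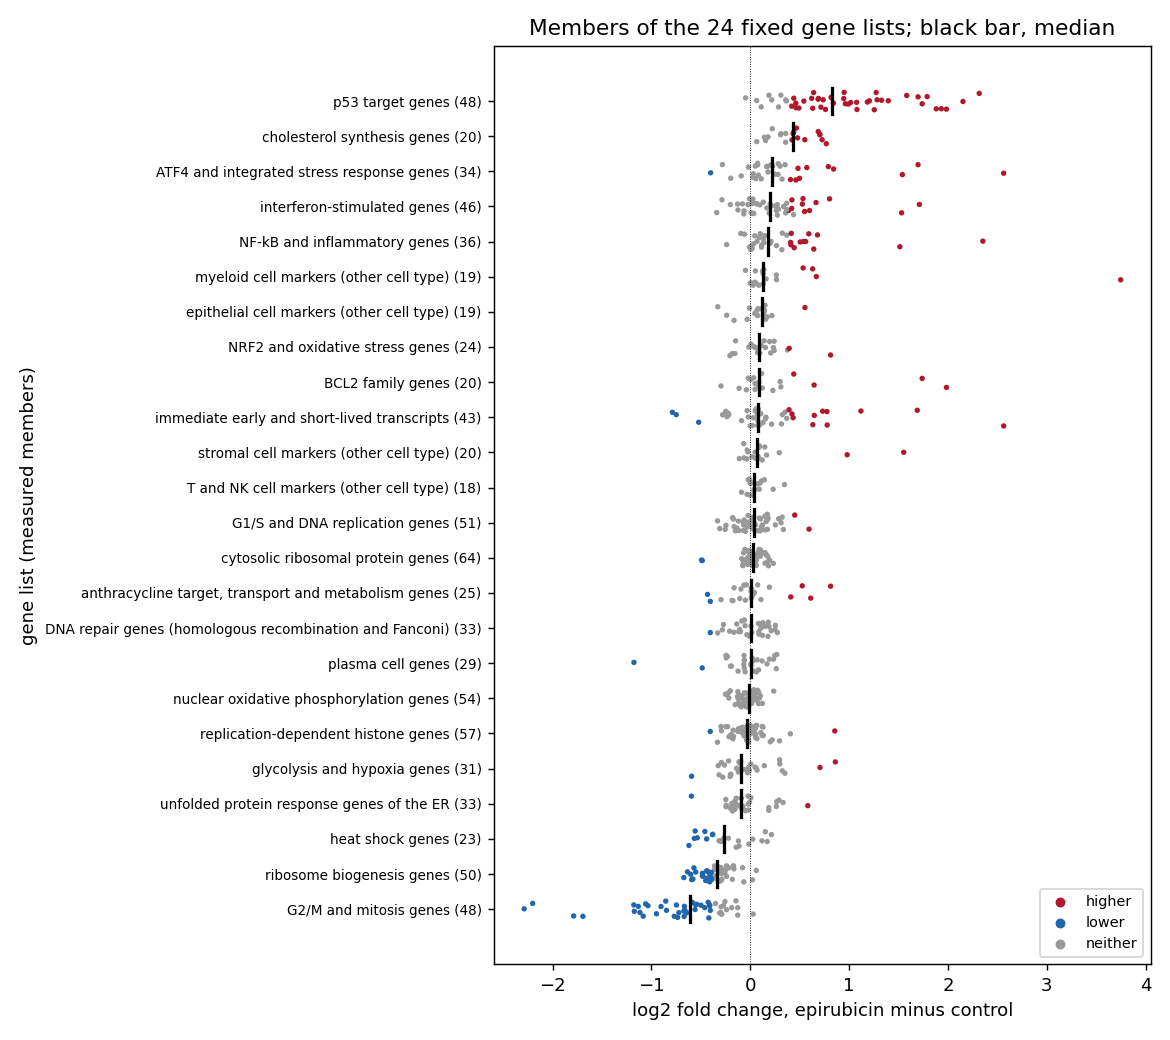
Each row is 1 of 24 gene lists fixed beforehand, with measured members in parentheses, and each point is a member's log2 fold change (epirubicin minus control), red if called higher, blue if called lower and grey otherwise. Black bars are medians, which run from -0.61 for the G2/M list to 0.83 for the p53 list.

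Genes of ribosome biogenesis fell: 22 of 50 were lower and 0 higher. Their median was -0.34 (camera, adjusted p = 5.54e-26, and adjusted p = 0.0415 with an estimated correlation). POLR3G, a subunit of RNA polymerase III, fell by 0.67 on the log2 scale (SE 0.04; 1 of 2 probe sets, with a mean of -0.44 over both), and the nucleolar protein gene NOP16 by 0.64 (SE 0.03; 2 of 3 probe sets). MYC, a transcription factor that drives growth genes, was lower as well (-0.52, SE 0.03, limma adjusted p = 0.000123). Of 64 cytosolic ribosomal protein genes, 2 were lower and 0 higher (median 0.02, camera, adjusted p = 0.250). They were RPL35A (-0.49, SE 0.04), with 1 of 3 probe sets called and a mean over probe sets of -0.13 that was not called, and RPL27A (-0.49, SE 0.10), a dim probe set named after its value was seen.

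Of 23 heat shock genes, 7 were lower and 0 higher. Their median was -0.27 (camera, adjusted p = 2.36e-07, and adjusted p = 0.0212 with an estimated correlation). CHORDC1 and FKBP4, cochaperones of HSP90, fell by 0.62 (SE 0.05) and 0.57 (SE 0.04; 2 of 3 probe sets) on the log2 scale. Of 33 genes of the unfolded protein response of the endoplasmic reticulum, 31 did not pass. The oxidase gene ERO1B was higher (0.58, SE 0.06; 3 of 4 probe sets) and SDF2L1, an ER chaperone cofactor, lower (-0.60, SE 0.04). The list shifted downward by a median of -0.10 (camera, adjusted p = 0.00568), a call lost with an estimated correlation (adjusted p = 0.139 with an estimated correlation).

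ATF4 and integrated stress response genes rose, with 10 of 34 higher and 1 lower. Their median was 0.22 (camera, adjusted p = 1.44e-06, and adjusted p = 0.0206 with an estimated correlation). ATF3 and SESN2, an inhibitor of mTORC1 signalling, led the list, SESN2 at 3.24-fold (log2 1.70, SE 0.05); it also stands in the p53 list. The amino acid transporter gene SLC7A5 was lower (-0.40, SE 0.03; 1 of 2 probe sets) and close to the fold threshold. In this list the amino acid synthesis gene ASNS, chosen after its value was seen, was not called (0.17).

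Cholesterol synthesis genes rose: 11 of 20 were higher, 0 lower, and the fold change of all 20 was above 0. Their median was 0.43 (camera, adjusted p = 9.09e-12, and adjusted p = 0.0156 with an estimated correlation). The sterol transport protein gene STARD4 rose 1.70-fold, from 5.73 ± 0.06 to 6.50 ± 0.07, and the sterol desaturase gene SC5D 1.65-fold, from 7.67 ± 0.06 to 8.40 ± 0.06 (SD, n = 3). HMGCS1, chosen after its value was seen, rose 1.63-fold. STARD4 was called on all 5 of its probe sets and SC5D on all 4.

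Inflammatory and interferon genes rose in part. Of 36 NF-kB and inflammatory genes, 12 were higher and 0 lower (median 0.17, camera, adjusted p = 2.36e-07, and adjusted p = 0.0195 with an estimated correlation). They were led by TNFSF9 and the chemokine gene CCL2, which rose 2.85-fold from 4.50 ± 0.02 to 6.01 ± 0.08 (SD, n = 3). Of 46 interferon-stimulated genes, 11 were higher, 12 when adjusted over the list alone, and 0 lower. Their median was 0.20 (camera, adjusted p = 5.99e-05, and adjusted p = 0.0415 with an estimated correlation). LAMP3 rose 3.27-fold and the chemokine gene CXCL10 2.89-fold, from 8.22 ± 0.05 to 9.76 ± 0.03 (SD, n = 3). The list did not move as one. IFIT1 was not called (0.17) and OAS2 lay at -0.13, both chosen after their values were seen.

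Of 43 immediate early and short-lived transcripts, 11 were higher and 3 lower (median 0.08), a call lost with an estimated correlation (camera, adjusted p = 0.00726, and adjusted p = 0.0676 with an estimated correlation). ATF3 and the MAP kinase phosphatase gene DUSP10 (3.22-fold, log2 1.69, SE 0.07) rose. MYC fell, as did ID1, an inhibitor of basic helix-loop-helix factors (-0.79, SE 0.05), and the transcription factor gene KLF2 (-0.75, SE 0.03).

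Plasma cell genes were mostly not called: of 29, 0 were higher, 2 lower and 27 neither (camera, adjusted p = 0.323). The 2 were CD38, 2.26-fold lower, from 6.42 ± 0.04 to 5.25 ± 0.08, and IRF4, a transcription factor on which myeloma cells depend, 1.40-fold lower, from 11.24 ± 0.02 to 10.75 ± 0.01 (SD, n = 3). XBP1, a transcription factor of secretory plasma cells, differed by -0.24 (CI -0.31 to -0.17), under the fold threshold. The list's median was 0.005, above 0, while its mean and its test pointed downward. NR3C1, which encodes the glucocorticoid receptor, was not called (0.13, CI -0.01 to 0.28, limma adjusted p = 0.159).

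**Figure D3:**
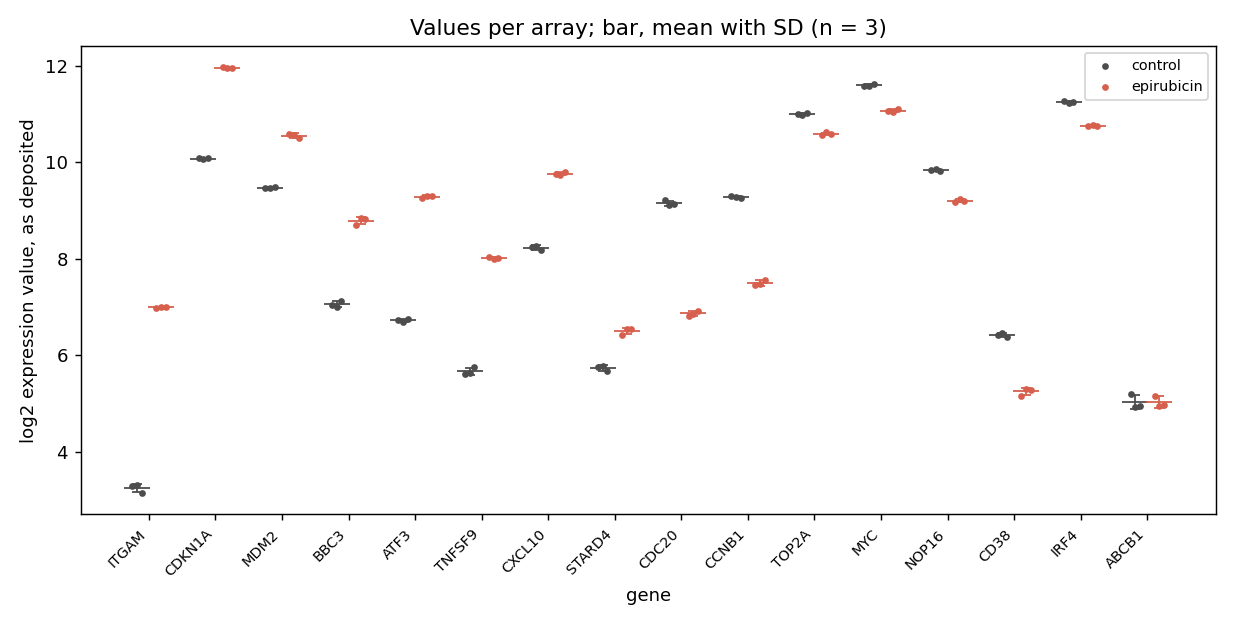
Log2 expression values of 16 genes per array, grey for control and red for epirubicin, with points for the 3 arrays of each group and bars for mean and SD. ITGAM moves from 3.25 to 6.99 and CDKN1A from 10.07 to 11.95, CDC20 from 9.15 down to 6.86, and ABCB1 lies at 5.02 and 5.03.

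Of 25 genes of anthracycline targets, transport and metabolism, 4 were higher and 2 lower, and the list was not called (camera, adjusted p = 0.736). Its median of 0.01 and mean of 0.03 lay above 0, with the test's direction, relative to all other genes, downward. The quinone reductase gene NQO1 (0.81, SE 0.04) and AKR1C3, an aldo-keto reductase (0.61, SE 0.04; 1 of 2 probe sets), were higher. So were the carbonyl reductase gene CBR3 (0.53, SE 0.05) and the efflux transporter gene ABCG2 (0.41, SE 0.04; 1 of 2 probe sets), both named after their values were seen. The drug target TOP2A was lower on all 3 of its probe sets (-0.40, SE 0.03, limma adjusted p = 0.000245), and also stands in the G2/M list. The efflux transporter gene ABCC4 was lower by -0.43 (SE 0.05; 3 of 4 probe sets). TOP2B was not called (-0.18, CI -0.25 to -0.10), and ABCB1, which encodes P-glycoprotein, was not called (0.01, CI -0.20 to 0.22, limma adjusted p = 0.953).

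In 24 genes of NRF2 and oxidative stress, 2 were higher, NQO1 and the autophagy receptor gene SQSTM1 (0.39, SE 0.03; 4 of 5 probe sets), and 0 lower. The shift (median 0.09, camera, adjusted p = 0.0258) was lost with an estimated correlation (adjusted p = 0.139 with an estimated correlation) and without epirubicin replicate 3 (adjusted p = 0.0593). Of 31 glycolysis and hypoxia genes, 2 were higher and 1 lower, with a median of -0.09 (camera, adjusted p = 0.0449; adjusted p = 0.129 with an estimated correlation). The higher genes were BNIP3L, a mitophagy receptor (0.86, SE 0.04), and the angiogenic factor gene VEGFA (0.70, SE 0.03; 3 of 10 probe sets), and the lower was HK2, which encodes hexokinase 2 (-0.59, SE 0.03; 1 of 2 probe sets). Leaving out control replicate 1 or 2, or epirubicin replicate 1 or 3, ended the call of that list, with adjusted p of 0.0678, 0.0589, 0.0700 and 0.0611. Of 54 nuclear genes of oxidative phosphorylation, 0 were called in either direction. Their log2 fold changes, from -0.25 to 0.24, all lay under the fold threshold, whatever their p-values. The median was -0.01 (camera, adjusted p = 0.0685, 0.0325 without epirubicin replicate 2, and 0.0161 to 0.515 over 12 alternatives with camera).

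Markers of other cell types moved with epirubicin in the myeloid list. Of 19 myeloid markers, 4 were higher and 0 lower: ITGAM, the costimulatory ligand gene CD86 (0.67, SE 0.04; 4 of 5 probe sets), and, named to complete the count after their values were seen, CD68 (0.63, SE 0.05; 1 of 2) and S100A9 (0.53, SE 0.10). The median was 0.13, and the call was lost with an estimated correlation (camera, adjusted p = 0.00520, and adjusted p = 0.0676 with an estimated correlation). Of 20 stromal markers, 2 were higher and 0 lower. ACTA2, smooth muscle actin, rose by 1.55 (SE 0.25) on 1 of 3 probe sets with an SD of 0.54 among control arrays, and the fibronectin gene FN1 by 0.98 (SE 0.04; 6 of 8 probe sets). Their means over probe sets were 0.58 and 0.56. Of 19 epithelial markers 1 was higher, the laminin gene LAMB3 (0.55, SE 0.03, 1 of 2 probe sets), and 0 lower. Of 18 T and NK cell markers 0 were called, as their log2 fold changes, from -0.09 to 0.35, all lay under the fold threshold. Neither the stromal, the epithelial nor the T and NK list was called (camera, adjusted p = 0.185, 0.250 and 0.357).

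Of the 24 lists, 14 passed the threshold, 9 upward and 5 downward. With an estimated correlation 8 lists kept an adjusted p under 0.05: p53 targets, G2/M, cholesterol synthesis, NF-kB, ATF4, heat shock, interferon and ribosome biogenesis. Of the 6 other lists that had passed, over 12 alternatives each with camera, the adjusted p ran from 0.00355 to 0.129 for the BCL2 family, 0.00230 to 0.139 for the unfolded protein response, 0.00420 to 0.0676 for immediate early genes, 0.0353 to 0.129 for glycolysis and hypoxia, 0.00801 to 0.139 for NRF2 and 0.000425 to 0.0676 for myeloid markers. Among the named genes, NBN, ABCC4, ERO1B, SLC7A5, VEGFA, HK2 and LAMB3 fell short of the 1.3-fold threshold as means over their probe sets (-0.37, -0.33, 0.35, -0.25, 0.33, -0.32 and 0.38), TOP2A and SLC7A5 after quantile normalization, and SQSTM1 after median centring. Wherever a list is given with 0 members called in a direction, that count was also 0 in limma at an unadjusted p under 0.05 with the same fold threshold. Where no member reached that fold, as in the oxidative phosphorylation and the T and NK lists, this followed whatever the p-values.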

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

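All results in this part come from probe sets outside the gene comparison. Of the 1947 probe sets with no gene symbol in the annotation, 72 were called higher with epirubicin, by up to 2.19 on the log2 scale, and 45 were called lower, the largest at -0.87. Of the 1558 probe sets that name several genes, 47 were called higher, by up to 1.65, and 34 lower, the largest at -1.74. Over all 47481 probe sets 1735 were called higher and 1242 lower, so these shares were near or under those of all probe sets. The counts are therefore not particular to these probe sets. They were examined because no gene comparison used them, and no gene was named from them.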

How the results depend on the processing

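Gene counts depended most on the fold threshold and on how probe sets were turned into genes. With no fold threshold 2744 genes were higher and 2362 lower, and at 2-fold or more 85 and 19, as fewer or more genes pass by construction. Counting a gene when at least 1 of its probe sets was called, an alternative chosen after seeing the data, gave 694 lower genes against 376, and 969 higher against 765, which changed both the probe sets counted and the fit and adjustment; their shares were not told apart. With an estimated correlation 8 lists passed against 14, and with fry, which does not compare a list with other genes, 20. Centring each array on its median gave 646 higher and 485 lower, quantile normalization 779 and 352, and the mean of a gene's probe sets 576 and 353. Leaving out each array in turn gave 723 to 807 higher and 363 to 404 lower genes, 1642 to 1803 higher and 1208 to 1356 lower probe sets, and 12 to 15 lists. No pairing by replicate number was seen: deviations of same-numbered samples correlated at -0.059, -0.0004 and -0.007. Whether same-numbered samples were prepared or hybridized together cannot be told from these values. With the replicate number as a block 755 genes were higher and 372 lower, 1718 and 1228 probe sets, and 13 lists passed, the glycolysis list (adjusted p = 0.0533) no longer among them. Among the named genes and the lists no called direction reversed, which was not examined for the other genes; the uncalled ABCB1 and MCL1 changed sign in some. Of 704 alternatives for the named genes 692 kept their side of the threshold, and 12, of MET, NBN, ABCC4, TOP2A, ERO1B, SLC7A5, RPL35A, VEGFA, HK2, SQSTM1 and LAMB3, fell short of it. Of 289 for the lists with camera 270 kept it, 3 newly passed and 16 no longer did; fry asks another question and is left out here. BCL2 family genes lost their call with the mean of probe sets (adjusted p = 0.0764). Oxidative phosphorylation gained one when arrays were centred (0.0161), and histones after quantile normalization (0.0292, range over 12 alternatives with camera to 0.260). The cause was not tested. The offset before taking logs was not run, as the values were already on a log2 scale. Signal over background could not be measured, so the lowest levels limit folds such as that of ITGAM.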

Other observations

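The tests of mixed myeloid cells, of a missing vector and of the interferon list without shared members were chosen after the results were seen. The groupings by symbol and by neighbour were added after the gene results, and genes in this part were named after their values were seen. Grouping the 17534 genes by the letters before the first digit of their symbol gave 309 groups of at least 8 members, tested as the lists were. The TCEAL genes of the X chromosome, which encode proteins related to a transcription elongation factor, rose in 5 of 9 members (median 0.43, camera, adjusted p = 0.00636, and adjusted p = 0.640 with an estimated correlation), among them TCEAL3 at 0.67 and TCEAL9 at 0.65. The cytidine deaminase genes of the APOBEC group had a median of 0.32 (adjusted p = 0.00459, and adjusted p = 0.640 with an estimated correlation), with 3 of 8 higher: APOBEC3H rose 2.66-fold (log2 1.41, SE 0.03), APOBEC3G by 0.46 (1 of 2 probe sets) and APOBEC3C by 0.39. Genes of the late cornified envelope, a skin structure, rose in 3 of 18 members (adjusted p = 0.0150, and adjusted p = 0.640 with an estimated correlation): LCE1E at 1.90, LCE1C at 1.86 and LCE1B at 0.76. Groups shifted downward with the preset correlation included RNA polymerase subunits (POLR, median -0.17), the CCT chaperonin (-0.26) and the SRSF splicing factors (-0.19), with 3 of 28, 1 of 9 and 1 of 11 members called lower (adjusted p = 0.651, 0.640 and 0.640 with an estimated correlation). In all, 32 groups passed with the preset correlation and 0 with an estimated one in camera, where the lowest adjusted p was 0.640 and 22 groups lay under 0.05 unadjusted.

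CD70, the ligand of CD27 and the chromosomal neighbour of TNFSF9, rose 2.17-fold (log2 1.12, SE 0.03). FAS, which encodes a death receptor, rose 2.99-fold (log2 1.58, SE 0.04). CD80, like CD86 a ligand of CD28, rose by 0.79 (4 of 5 probe sets). ITGB2, whose product pairs with that of ITGAM in Mac-1, was not called, at 4.30 and 4.27 (limma, adjusted p = 0.884).

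By its brightest probe set ITGAM rose more than any other called gene, though as a mean over probe sets it rose by 2.35, less than GADD45G at 2.74, and with CD86, CD68 and S100A9 it was 1 of the 4 myeloid markers called higher. Cells of the myeloid lineage mixed into the epirubicin cultures would bring their abundant transcripts along. The other 18 markers had a median of 0.13 (bootstrap 95% interval over markers, not cultures, 0.05 to 0.21). That lay below even the ITGAM probe set that changed least (0.79, CI 0.61 to 0.97). The list holds markers of several myeloid cell types, so cells of 1 type need not raise its median as much as ITGAM. The comparison therefore argues only against a mixture that raises most of these markers as much as ITGAM. LYZ went from 2.39 to 2.52, S100A8 from 3.39 to 3.44 and CD14 from 2.79 to 2.95, all uncalled. Whether the brightest ITGAM probe set reads another transcript stays open: the other probe sets rose by 2.52 and 0.79, and the latter missed the 2-fold bound set beforehand yet lay above the 1.3-fold limit that the explanation allows. An induction of ITGAM in the myeloma cells themselves is a hypothesis that these data do not settle.

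The call of the interferon-stimulated genes did not rest on genes shared with the p53 and NF-kB lists, of which there was only 1, TRIM22. Without it, in the 1 setting run, the adjusted p in camera was 9.57e-05. Leaving out 1 of 46 members could hardly change the call, so this does not separate the rise from a p53 or NF-kB response. For the full list the adjusted p was 5.99e-05, and 1.52e-07 to 0.0415 over its alternatives with camera. Whether the epirubicin cells had received the vector cannot be told apart from the drug, since 0 arrays carry labels naming both. A response of the cells to epirubicin stays a hypothesis.

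Neighbouring genes were called together more often than in random gene orders. Of 17138 pairs of adjacent genes 63 were both higher, against a mean of 33.1 (95% range 23 to 44) over 10000 random orders (permutation p = 1e-04, the smallest they can give), among them TNFSF9 with CD70 and ACTA2 with FAS. The excess was not confined to neighbours with like symbols: 51 pairs whose symbols differ in their first 3 letters were both higher against 29.8 (permutation p = 2e-04). This rule measures no sequence and also counts MX1 and MX2 as different, so it cannot exclude sequence shared between related neighbours. Whether neighbours move together in general on these arrays stays open: among pairs that differ in their first 3 letters the ratio to random orders was 1.92 for pairs both lower (14 against 7.27, permutation p = 0.015) and 1.71 for pairs both higher, but over all pairs it was 1.73 (14 against 8.09, permutation p = 0.034) and 1.90. The random orders spread the calls over all 17162 genes, bright or dim. If genes that can hardly be called lie next to each other, an excess can arise without joint regulation, which was not tested. In simulated data the test called 20 of 20 draws with 40 planted pairs and 2 of 20 without. Those draws also placed calls at random over all genes, so they do not bear on that limit.

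Other splits of the 6 arrays into 3 and 3 number 10 with the real one, too few for a share under 0.05. In each count the real split alone (1 of 10) reached its own value. It gave 1141 genes against 0 for the highest other split (1152 against 9 at an unadjusted p under 0.05 in limma), and 2977 probe sets against 0 (3040 against 29 unadjusted). It gave 14 lists against 9 and 32 symbol groups against 12, so camera with the preset correlation called lists also where the groups were mixed. Every other split mixes the groups unevenly, so it keeps part of the real difference and moves the rest into the spread. The counts of the other splits, 0 included, therefore do not show what arises without a difference.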
